A study of Arabidopsis thaliana with 16 samples.

How the data were processed

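The measurements were small RNA reads from Arabidopsis thaliana of the Col-0 background. Per the labels, 10 libraries came from total RNA (Trizol) of 3-week-old plants grown in soil under 16 h light and 8 h dark, with library preparation at a company. They were wild type (WT) without UV (n = 2), WT 30 min after 3000 J/m2 of UV-C (n = 4), the nrpd1a mutant without UV (n = 2) and nrpd1a after UV (n = 2). A further 6 libraries, 1 per condition, came from 2-week-old plants grown in vitro that carried DDB2 with a FLAG tag: input RNA, an AGO1 immunoprecipitate and a DDB2 immunoprecipitate, each at time 0 and 15 min after UV. Per the labels, the AGO1 immunoprecipitates list the same anti-FLAG gel as the DDB2 ones, and the treatment text shared by all libraries names 30 min although these 6 carry 15 min, so both points are open here. All 16 samples were assigned to groups from their labels.

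The authors' deposited values for the 10 libraries were raw read counts, not normalized, for each distinct sequence at each genome position and strand, in 5 length classes (21, 22-23, 24-25, 26-30 and 31-40 nt). Per the submitters' processing notes, CASAVA 1.8.2, Bowtie and bedtools were used with TAIR10, and per the file headers the positions were converted from BED to GFF. The number of mismatches and the treatment of sequences with several matches are not given in the sources used here. The counts themselves showed that a sequence with several matches was listed at each of them with its full count. The 31-40-nt counts of nrpd1a after UV, library 2, were 0 at every position and were not used. For the 6 immunoprecipitation libraries the deposited lists held only genome positions of 21-nt sequences, a unit other than reads, with no count per position and every strand given as plus, and per the file headers they hold small RNAs that match intergenic regions. The share of a category there is therefore a share of listed positions, and the depth in reads is unknown.

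Most annotated miRNA loci held no read: of 326 annotated MIR genes, 301 had 0 reads in the 10 libraries and 19 had at least 10 reads in 2 libraries. Whether matches to miRNAs were left out before deposit is not given in the sources used here. If they were, length-class shares, the TAS share of 21-nt reads and values per 1000000 reads are relative to totals without most miRNA reads. The plan, made before the data were examined together with all tests, gene lists and alternatives except those named below as added, was to scale the comparison of genotypes to miRNA reads. This was not possible, nor could the 6 miRNA lists be tested, since 0 of their members passed the read filter. The 21-nt reads at the 8 TAS genes (loci of trans-acting siRNAs, made without RNA polymerase IV) took the place of the miRNA reads, a choice made after the data were examined, so values of TAS genes between genotypes are relative to the TAS total by construction. The planned total over 5 length classes was replaced by the 4 classes from 21 to 30 nt, because 1 library lacks the longest class. The share of 31-40-nt reads is given relative to that total.

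Reads were counted in 1000 bp windows of the nuclear and chloroplast sequences and in annotated genes (midpoint of the match within the gene, both strands summed) with the TAIR10.1 annotation, whose nuclear lengths equal those of TAIR10. The mitochondrial sequence differs between the builds, so mitochondrial positions were only totalled and the mitochondrial gene list had 0 members. The annotation has no transposable element class, and the planned category was replaced by genes of the pseudogene type. Windows and genes with at least 10 reads in at least 2 libraries of a fit were tested with the quasi-likelihood test of edgeR 4.0.16, with TMM scaling for UV effects and TAS reads for genotypes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. UV effects were fitted within each genotype (2 against 4 WT libraries, 2 against 2 nrpd1a libraries), the genotype effect over all 10 libraries with treatment as a covariate, and the difference of UV effects as the interaction term over all 10. Gene lists were tested with camera (limma 3.58.1) with its preset correlation and with an estimated correlation, and calls were also adjusted over the list alone. Genes that share sequences, such as copies of a tRNA gene, hold the same reads and are not independent.

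The 17 gene lists fixed in advance were the 6 miRNA lists, TAS genes, PPR genes of the chromosome 1 siRNA cluster, auxin receptor genes, ARF and MYB genes targeted by TAS3 and TAS4, RNA silencing genes, DNA repair genes, UV and stress-response genes, nuclear photosynthesis genes, chloroplast-encoded genes, mitochondrion-encoded genes, and rRNA, tRNA, snRNA and snoRNA genes. Named genes followed a fixed rule: up to 10 with the largest rise and 10 with the largest fall per comparison among those with adjusted p under 0.05, groups that do not overlap and a mean of at least 5 CPM (counts per 1000000 counts of the library size), up to 4 members of each list with the lowest adjusted p, and AGO1, DDB2, NRPD1 and all TAS genes. For windows the rule took the 3 largest rises and 3 largest falls. Where the rule gave identical copies of a tRNA gene, some copies stand for the rest.

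Shares of reads per length class and annotation category were compared by exact two-sided permutation of labels within the other factor (90 arrangements, smallest possible p = 0.0111), adjusted by Benjamini-Hochberg over the classes or categories. Windows higher after UV in WT were compared in sequence and position with 10000 random lists of tested windows matched on mean count. Listed positions of the immunoprecipitation libraries were given as shares with exact (Clopper-Pearson) 95% binomial intervals, without a test, since each condition had 1 library. The intervals treat each position as an independent draw, although a sequence with several matches may be listed at each of them. They may therefore be too narrow even for counting error, and they do not cover variation between libraries. The planned choice of miRNA and TAS genes by ratio to input could not be applied, since 0 of 334 such genes held a listed position. Totals over tRNA genes and the counts by strand, with each distinct sequence counted once, were added after the windows had been examined. The unit there is rpm, reads per 1000000 reads of 21 to 30 nt. Folds of tRNA reads come from the mean log2(rpm + 1) of the libraries, with a pseudocount of 1, and log2 values of the groups of genes by strand from reads with 1 added before scaling.

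The total of 21-30-nt reads per library was 4306770 to 5695700 in WT and 2961425 to 4686159 in nrpd1a. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom 1.29 to 5.41 over windows with many 21-nt reads), so none was counted as a repeat of another. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The reads are PCR products without molecular identifiers, so intervals and floors cover counting error only. Where all libraries of a group had 0 reads, a fold is given as a bound against a floor of 3 reads over the whole group. Each test was tested on simulated counts: of windows changed 4-fold, 99.0% were recovered for the UV effect in WT at 21 nt (12983 windows) and 11.0% for the interaction at 24-25 nt (30101 windows), where 25.0% of calls were false. Of genes, 98.0% of those changed 4-fold and 57.0% of those changed 2-fold were recovered for the UV effect in WT (4012 genes).

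Alternatives were DESeq2 1.42.0, its size factors in the edgeR fit, total reads or TAS reads as library size, no filter, a filter of 30 reads, only sequences listed at a single position, windows of 500 bp, the sense strand only, the replicate number as a block, and each library left out in turn. Added after the data were examined were TAS scaling of the UV effects, counting each distinct sequence once per feature, leaving out sequences that also match tRNA, rRNA or chloroplast sequence, both together, and annotation categories per TAS read. Computation used Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3 (with data.table, version 1.17.8).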

Results

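Small RNAs of Arabidopsis thaliana were sequenced before and after UV-C, a short-wave ultraviolet that joins neighbouring pyrimidines in DNA, to follow small RNAs linked to the recognition of UV lesions. WT plants gave 2 libraries without UV and 4 libraries 30 min after 3000 J/m2 of UV-C. The nrpd1a mutant, which lacks the largest subunit of the siRNA-precursor polymerase RNA polymerase IV, gave 2 libraries without UV and 2 after UV. The 6 WT libraries held 4306770 to 5695700 reads of 21 to 30 nt with 1242873 to 1490104 distinct sequences. The 4 nrpd1a libraries held 2961425 to 4686159 reads with 271673 to 368892 distinct sequences. A separate set of 6 libraries, 1 per condition, listed 21-nt positions from input RNA and from AGO1 and DDB2 immunoprecipitates at time 0 and 15 min after UV. AGO1 is the main carrier of miRNAs, and DDB2 is a DNA damage sensor of nucleotide excision repair.

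The first comparison asked what the nrpd1a mutation removed. The targeted gene NRPD1A (AT1G63020) held 14 and 15 reads of 21 nt in WT without UV, 20, 13, 12 and 3 in WT after UV, 11 and 10 in nrpd1a without UV, and 13 and 17 in nrpd1a after UV. Small RNA reads at a gene do not measure its transcript, so these reads did not test the labels. DDB2 held 1 read in a single library and AGO1 (AT1G48410) 127 to 276 reads. Neither NRPD1A (log2 -0.23, adjusted p = 0.6) nor AGO1 (log2 0.28, adjusted p = 0.185) differed between genotypes in the edgeR quasi-likelihood test. The share of 24-25-nt reads, the siRNA class of RNA polymerase IV, fell from 49.4% ± 0.995 (SD, n = 2) in WT to 23.6% ± 2.67 (n = 2) in nrpd1a without UV. After UV it fell from 46.7% ± 2.48 (n = 4) to 23.8% ± 0.0246 (n = 2). The mean difference was -24.4 percentage points (exact permutation within treatment, 90 arrangements, p = 0.0111, the smallest they can give, adjusted p = 0.0185 over 5 classes). The shares of 21-nt reads (by 8.69 points, adjusted p = 0.0185), 26-30-nt reads (by 13.5 points, adjusted p = 0.0185) and 31-40-nt reads (by 1.76 points, adjusted p = 0.0417) rose in nrpd1a in the exact permutation tests, as shares of a total from which 24-25-nt reads were lost. In percent of TAS reads, the scale used between genotypes below, the 21-nt reads differed by -0.394 (exact permutation, adjusted p = 0.989), the 26-30-nt reads by 85.3 (adjusted p = 0.264) and the 31-40-nt reads by 15.2 (adjusted p = 0.111), so none of these rises passed. The 22-23-nt share differed by 2.14 points (exact permutation, adjusted p = 0.0778), but per TAS read 22-23-nt reads fell (by 96.9 percent of TAS reads, exact permutation, adjusted p = 0.0278). The 22-23-nt share passed without library 2 of nrpd1a without UV. The 31-40-nt share did not pass without each library of the untreated groups or of WT after UV (1.53 to 2.00 points).

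**Figure D1:**
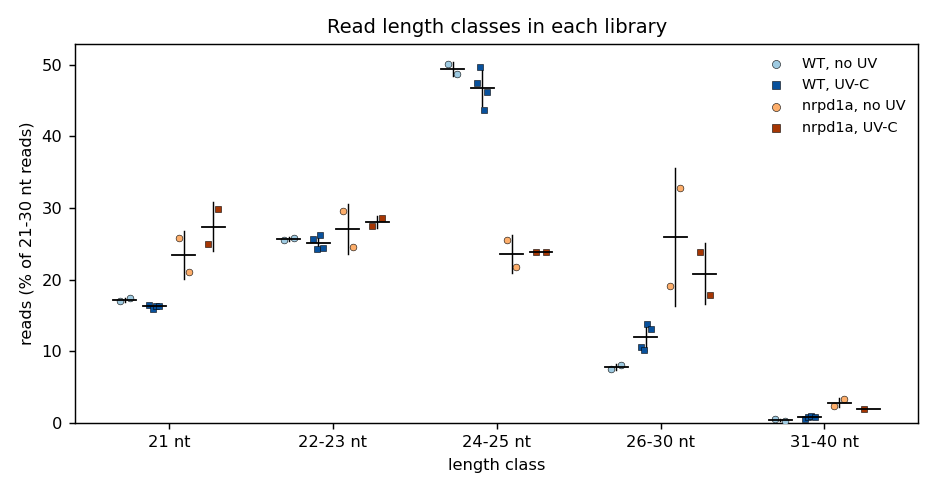
Share of reads in each length class (y axis, percent of the reads of 21 to 30 nt; x axis, length class in nt) for the 10 libraries, with points for libraries, lines for group means and bars for ± SD. The 24-25-nt class holds 46.7% to 49.4% on average in the WT groups and 23.6% to 23.8% in the nrpd1a groups, and the 26-30-nt class of nrpd1a without UV spreads widely (SD 9.58).

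Windows of 1000 bp lost most of their 24-25-nt and many of their 21-nt reads in nrpd1a. At 24-25 nt, 29378 of 30502 tested windows were lower and 150 higher, with a median log2 of -7.15 (-6.45 with the 7792 windows at 0 reads in nrpd1a set to their bound). At 21 nt, 11205 of 13937 windows were lower and 422 higher, with a median log2 of -3.84 (-3.76 with 1426 windows at their bound). The largest 24-25-nt losses lay at 1:5965001-5966000 (3835 reads in the 6 WT libraries, 0 in the 4 nrpd1a libraries, at least 996-fold lower), at 2:14386001-14387000 with AT2G34060 (2786 reads to 0, at least 723-fold) and at 4:595001-596000 (2739 reads to 0, at least 711-fold). At 21 nt the windows 5:744001-745000 (987 reads to 0, at least 256.3-fold), 3:11726001-11727000 with the pseudogene AT3G29805 (893 reads to 0, at least 232-fold) and 4:17655001-17656000 with the pseudogene AT4G37570 (885 reads to 0, at least 230-fold) fell most. These reads and bounds are as listed at each match. With each sequence counted once per window, WT reads in the same order were 2464, 1845 and 2739 at 24-25 nt. At 21 nt they were 604, 525 and 702, so most of these bounds would be lower. Some windows rose: 3:11482001-11483000, which holds the non-coding RNA gene AT3G00580, went from 12.04 ± 1.95 CPM (SD, n = 2) to 425 ± 21.9 (n = 2) at 21 nt without UV (log2 4.97, SE 0.20, adjusted p = 2.47e-16). It rose at 24-25 nt too (log2 3.71, SE 0.14). The neighbouring window 3:11481001-11482000 (log2 4.52, SE 0.21) and 3:15420001-15421000 with the pseudogene AT3G43524 (log2 4.33, SE 0.20) rose at 21 nt. At 24-25 nt, 2:16588001-16589000 with MIR8121 and the cell wall gene CYT1 (log2 2.87, SE 0.14) and 4:13296001-13297000 with AT4G26255 (log2 2.18, SE 0.18) rose. The fall of the median depended on the scale. TMM, which assumes that most windows do not change, moved the median by 2.16 at 21 nt (3604 higher, 8213 lower) and by 6.07 at 24-25 nt (2585 higher, 8368 lower). Total reads moved it by 0.598 at 21 nt (2050 higher, 10489 lower) and 0.531 at 24-25 nt. With sequences listed at a single position only, 1654 windows were called at 21 nt and 17913 at 24-25 nt. At 21 nt no filter gave 21780 windows and a filter of 30 reads 4723.

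Among annotated genes, 21-nt reads of 2318 genes fell and of 116 rose in nrpd1a (4518 tested, median log2 -0.98, and -0.98 with 224 genes at their bound). Pseudogenes made up most of the losses, with 1433 of 1528 lower and 22 higher, while of protein-coding genes 698 of 1892 were lower and 66 higher. The largest falls were the pseudogenes AT3G29805 (845 reads in WT, 0 in nrpd1a, at least 219-fold) and AT4G37570 (567 reads to 0, at least 147-fold). Next came AT1G48422 (566 to 0), AT5G35860 (481 to 0), AT4G06535 (456 to 0), AT2G11815 (374 to 0), AT5G38037 (356 to 0), AT3G28005 (347 to 0), AT5G33075 (289 to 0) and AT4G16640 (288 to 0), with bounds down to at least 74.8-fold. These reads and bounds are as listed at each match. With each sequence counted once per gene, WT reads were 205 at AT3G29805, 384 at AT4G37570, 163 at AT5G35860 and 142 at AT5G38037. They were 220 at AT3G28005 and 401 at AT4G06535, so the bounds of all these genes would be lower. At the others they were nearly or fully unchanged. The largest rises were AT3G00580 (log2 4.29, SE 0.40), AT2G10975 (log2 4.16, SE 0.26, 1.35 ± 0.805 to 38.7 ± 4.94 CPM without UV, SD, n = 2 each). RALFL4, a gene of the RALF peptide family, rose too (log2 3.25, SE 0.18, adjusted p = 4.52e-11, 31.8 ± 2.02 to 273 ± 20.3 CPM). AT1G31163 rose as well (log2 2.82, SE 0.18). With sequences listed at a single position, however, RALFL4 (log2 -6.27) and AT1G31163 (log2 -2.54) changed sign, and so did AT1G31163 on its sense strand alone (log2 -2.46). AT5G19633, AT2G13400, AT1G40121, AT1G36770, AT5G33150 and AT1G38194 rose by log2 2.45 to 3.10. Total reads as library size moved the median of genes by 0.634 (1582 higher, 2072 lower) and TMM by 0.384 (1129 higher, 2165 lower). No filter gave 4376 genes, a filter of 30 reads 1041, the sense strand alone 1503 and sequences at a single position 499, most of them lower.

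Of the fixed lists, 2 of 8 TAS genes rose in nrpd1a relative to the TAS total, which the scaling holds fixed (2 adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.246 with an estimated correlation). They were TAS4 (AT3G25795, 3:9417551-9418705), whose siRNAs target MYB genes of anthocyanin synthesis (log2 1.39, SE 0.30, adjusted p = 0.000355), and TASIR-ARF (AT5G57735, log2 1.002, SE 0.24, adjusted p = 0.00134). TAS1A, TAS1B, TAS1C, TAS2, TAS3 and TAS3b lay between log2 -0.20 and 0.10, on that scale. Of chloroplast-encoded genes, 13 of 127 rose, and 112 with TMM and 122 with total reads as library size (0 adjusted over the list alone, camera adjusted p = 2.44e-14, adjusted p = 0.34 with an estimated correlation). Among them were psbF of photosystem II (log2 0.65, adjusted p = 0.00404) and the ribosomal protein gene rps18 (log2 0.61, adjusted p = 0.00275). Of rRNA, tRNA, snRNA and snoRNA genes, 3 of 675 rose and 5 fell, whereas 473 with TMM and 597 with total reads rose (0 adjusted over the list alone, camera adjusted p = 8.32e-24, adjusted p = 0.34 with an estimated correlation). They included the tRNA-Gly genes AT3G06105 (log2 0.9987, adjusted p = 0.00613) and AT1G60840 (log2 0.69, adjusted p = 0.02), and the spliceosomal RNA genes U4atac (log2 -0.79, adjusted p = 0.0032) and U4.8 (log2 -0.55, adjusted p = 0.0248). None of the 20 nuclear photosynthesis genes was called (0 adjusted over the list alone, 19 positive, camera adjusted p = 0.000411, adjusted p = 0.394 with an estimated correlation). Nor was any of 11 PPR genes (0 over the list alone, all 11 positive, camera adjusted p = 0.00816, adjusted p = 0.394 with an estimated correlation). The auxin receptor genes (0 of 3), the ARF and MYB genes (0 of 3) and the RNA silencing genes (0 of 4) had camera adjusted p = 0.27, 0.316 and 0.176, upward although their medians were -0.08, -0.23 and -0.14. The counts at an unadjusted p under 0.05 were 2512 for all genes, and DESeq2 called 2400.

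The second comparison asked which small RNAs changed 30 min after UV in WT. Reads of nuclear tRNA genes, the adaptors of translation, dominated the rise. They went from 14486 ± 232 (SD, n = 2) to 42163 ± 2518 reads (n = 4) per 1000000 reads of 21 to 30 nt (rpm), a 2.91-fold rise. Folds of tRNA reads come from mean log2(rpm + 1) and so differ from ratios of rpm means. In nrpd1a they went from 31435 ± 1149 (n = 2) to 74139 ± 2366 (n = 2), 2.36-fold. Reads of chloroplast tRNA genes differed by a mean log2 of -0.0015 (exact permutation, p = 0.989). Every treated library lay above every untreated library of its genotype for the nuclear total (mean log2 1.39, exact permutation within genotype, p = 0.0111, the smallest of 90 arrangements, adjusted p = 0.0222 over both genomes). Of 20 nuclear amino acid families, 18 rose (adjusted p = 0.0234 over 40 families of both genomes), led by tRNA-Trp (42.9 ± 1.34 to 440.0 ± 67.0 rpm in WT, 9.94-fold, and 7.55-fold in nrpd1a). Next were tRNA-Pro (512 ± 0.852 to 4054 ± 207 rpm, 7.89-fold and 5.84-fold) and tRNA-His (5.69-fold and 4.33-fold). The exceptions were tRNA-Met (1.10-fold and 0.997-fold) and tRNA-Tyr (1.19-fold and 0.916-fold). Among chloroplast families tRNA-Gln alone rose (1.74-fold and 1.94-fold). As part of a test of 10 annotation categories over 21-30-nt reads, tRNA (mean log2 1.39) and snRNA or snoRNA genes (mean log2 0.359) had p = 0.0111 in the exact permutation and adjusted p = 0.0556. Nuclear rRNA (mean log2 -0.183, exact permutation p = 0.378) and TAS genes (mean log2 0.132) did not differ detectably.

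**Figure D2:**
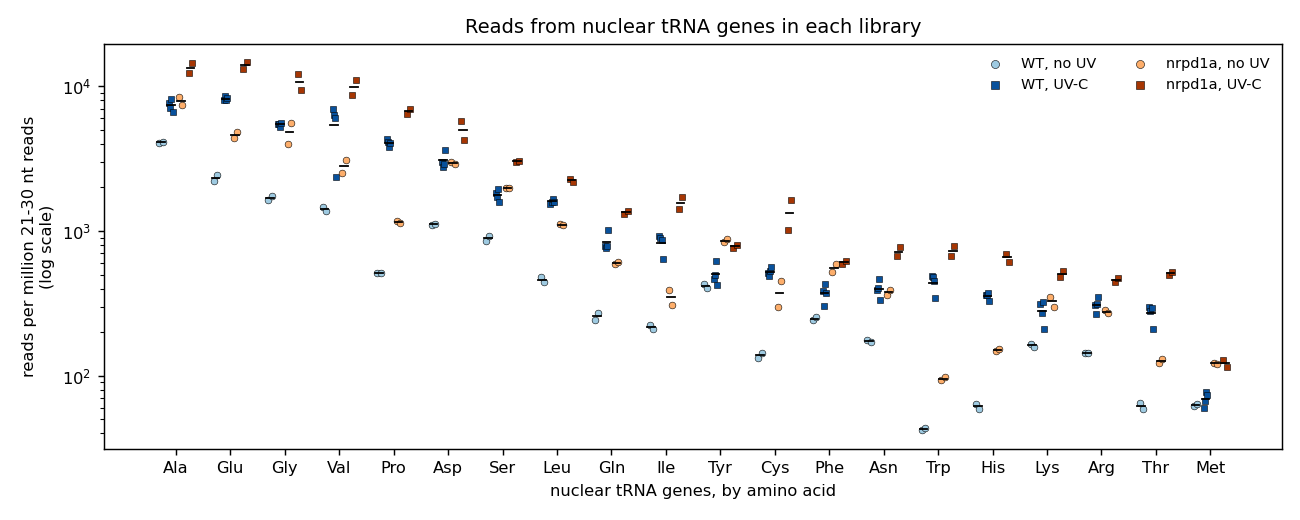
Reads of nuclear tRNA genes by amino acid (x axis) in rpm (y axis, log scale), each distinct sequence counted once, with points for the 10 libraries and lines for group means. Treated libraries lie above the untreated libraries of their genotype for 18 of 20 amino acids, and tRNA-Trp in WT goes from 42.9 to 440.0 rpm.

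The tRNA reads rose by part and length. Those inside the tRNA, away from both ends, rose 8.09-fold in WT (1732 to 14032 rpm) and 6.03-fold in nrpd1a. Those at the 3' end rose 4.04-fold and 4.07-fold, and those at the 5' end 2.20-fold and 1.83-fold (12719 to 27987 rpm in WT), each with p = 0.0111 in the exact permutation (adjusted p = 0.0222 over 6 parts). Reads of 26-30 nt rose 4.69-fold and 2.66-fold, and 21-nt reads 1.72-fold and 1.51-fold. The single sequence with the largest gain was the 24-nt 5' end of tRNA-Val, GGTTTCGTGGTGTAGTTGGTTATC, which matches 14 genes such as AT1G12510 (1:4267038-4267061, minus strand, TAIR10.1). It went from 300.4 ± 2.28 to 3004 ± 1706 rpm in WT and from 452 ± 67.1 to 5738 ± 1046 rpm in nrpd1a. The 23-nt 5' end of tRNA-Ala, GGGGATGTAGCTCAGATGGTAGA (15 genes, such as AT1G06610, 1:2025356-2025378), went from 1040 ± 55.1 to 3459 ± 304 rpm in WT. These sequences were chosen after their values were seen.

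By the planned windows, 327 of 13518 tested 1000 bp windows were higher and 8 lower at 21 nt after UV in WT, and 297 of the 327 held a tRNA gene (554 tested windows did). The window 3:6483001-6484000, with the tRNA-Thr gene AT3G18815, rose from 2.53 ± 0.267 (SD, n = 2) to 128 ± 42.5 CPM (n = 4; log2 5.63, SE 0.43, adjusted p = 9.33e-07), and 3:2105001-2106000, with the tRNA-His gene AT3G06665, rose by log2 5.35 (SE 0.33). The window 4:11974001-11975000, with the pseudogene AT4G22785 that resembles a tRNA-Lys, went from 0 reads in 2 libraries to 111 in 4, at least 16.6-fold higher. The windows 4:2177001-2178000 (log2 -1.49, adjusted p = 0.00229), 4:7891001-7892000 with AT4G13575 (log2 -1.48, adjusted p = 0.00108) and 5:10404001-10405000 (log2 -1.44, adjusted p = 0.00898) fell. At 24-25 nt, 199 of 30372 windows were higher, 192 of them with a tRNA gene, and 2 lower. The window 3:2105001-2106000 rose by log2 4.30 (SE 0.35), 3:3622001-3623000 with the tRNA-Pro gene AT3G11505 and 2:9137001-9138000 with the tRNA-Pro gene AT2G21360 by log2 4.12 (SE 0.19). The windows 2:7191001-7192000 (log2 -0.45, adjusted p = 0.017) and 4:7890001-7891000 (log2 -0.49, adjusted p = 0.0492) fell. Without sequences that also match tRNA, rRNA or chloroplast, 8 windows were called at 21 nt and 0 at 24-25 nt by edgeR (1930 at an unadjusted p under 0.05), with each sequence also counted once 20 and 1, and with sequences at a single position 19 and 17. Without library 4 of WT after UV, which differed from the other libraries of its group by 4.72 to 5.41 in chi-square per degree of freedom, 363 windows were called at 24-25 nt. Total reads as library size gave 540 windows there, and no filter 764.

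Among genes, 21-nt reads of 389 rose and of 8 fell after UV in WT (4148 tested; DESeq2 366 and 3). Nuclear tRNA genes gave 338 of the rises (of 582) and none of the falls. All tRNA-Pro (65 of 65) and tRNA-Gly (39 of 39) genes were called higher, and none of the tRNA-Tyr (0 of 65), tRNA-Ala (0 of 33), tRNA-Phe (0 of 17) or tRNA-Met (0 of 8) genes at this length. The tRNA-Thr genes AT3G18815 (3:6483940-6484013) and AT4G16105 (4:9108308-9108381) rose from 6.95 ± 1.22 (SD, n = 2) to 243 ± 74.1 CPM (n = 4; log2 5.12, SE 0.43, adjusted p = 1.12e-05). Their copies AT4G14415, AT1G49280, AT4G34975 and AT2G34985 rose by log2 4.89 to 5.03, and the tRNA-Pro genes AT1G08950, AT1G10440, AT1G59880 and AT3G21475 from 35.1 ± 4.17 to 685 ± 52.9 CPM (log2 4.28, SE 0.22, adjusted p = 1.09e-06). The pseudogene AT4G22785 (4:11974941-11975018) rose at least 16.2-fold, from 0 reads in 2 libraries to 111 in 4. TAS4 rose from 82.8 ± 16.3 to 248 ± 127 CPM (log2 1.58, SE 0.40, adjusted p = 0.0288), with 583 reads in library 4 and 243 to 275 in the others, a call that ended without either untreated library (adjusted p = 0.137 and 0.297). The gene of the Calvin cycle enzyme SBPASE (log2 -1.65, SE 0.44, adjusted p = 0.0373, 15.8 ± 0.241 to 4.93 ± 2.73 CPM) fell. So did the chloroplast translation factor gene SCO1 (log2 -1.15, SE 0.30, adjusted p = 0.033), the chloroplast trnR (log2 -1.22, SE 0.24, adjusted p = 0.0071, counted at both identical copies), AT2G14090, AT1G24851 and AT1G25180. SBPASE was not called without either untreated library (adjusted p = 0.186 and 0.23) or library 1 of WT after UV (0.0792), nor with TAS scaling (0.099). SCO1 was not called without either untreated library (adjusted p = 0.137 and 0.275), without library 1, 2 or 4 of WT after UV (0.0807, 0.076 and 0.0569), with total reads (0.0645), with TAS scaling (0.155) or by DESeq2 (0.153). Without untreated library 1 the calls of trnR (adjusted p = 0.121), AT1G24851 (0.104), AT1G25180 (0.164) and AT2G14090 (0.214) ended. Without untreated library 2 those of AT1G24851 (adjusted p = 0.161), AT1G25180 (0.189) and AT2G14090 (0.18) ended. AT1G25180 also lost its call without library 2 or 3 of WT after UV (0.0651 and 0.0551), and AT2G14090 without library 1, 3 or 4 (0.0663, 0.0657 and 0.063). By edgeR, 0 genes were called without sequences that also match tRNA, rRNA or chloroplast (217 at an unadjusted p under 0.05), with each sequence also counted once 2, and with sequences at a single position 17. TAS scaling moved the median of genes by 0.257 and of 21-nt windows by 0.225.

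Of the fixed lists, the rRNA, tRNA, snRNA and snoRNA genes had 338 of 653 members higher after UV in WT (370 adjusted over the list alone, median log2 1.06, camera adjusted p = 1.02e-58, adjusted p = 0.274 with an estimated correlation). Of 8 TAS genes, TAS4 alone rose (1 adjusted over the list alone, median -0.23, mean 0.04, camera downward with adjusted p = 0.387, adjusted p = 0.59 with an estimated correlation). The other TAS genes did not pass: TAS1A had log2 -0.23 (SE 0.15), TAS1C -0.36, TAS2 -0.18, TAS3 -0.24 and TASIR-ARF 0.19. None of 20 photosynthesis genes was called (0 adjusted over the list alone, 18 negative, median -0.21, adjusted p = 0.0928, adjusted p = 0.59 with an estimated correlation). Of chloroplast-encoded genes, 2 of 127, the trnR copies, fell (2 adjusted over the list alone, camera adjusted p = 0.00054, adjusted p = 0.59 with an estimated correlation). No PPR gene (0 of 11, all negative, 0.164), auxin receptor gene (0 of 3, TIR1 log2 -0.39, AFB2 -0.28, AFB3 -0.24), ARF or MYB gene (0 of 3, ETT -0.42, ARF4 -0.23, ARF2 0.08) or RNA silencing gene (0 of 4, AGO1 0.18, DCL1 -0.02, AGO2 -0.78, NRPD1A -0.47) was called, before or after adjustment over the list alone. With edgeR, 615 genes in all had an unadjusted p under 0.05, and DESeq2 called 369. Of 28 DNA repair genes 0 had enough 21-nt reads for the test. Of 18 UV and stress-response genes only TT4, the chalcone synthase of flavonoid synthesis, did (log2 0.24, not called).

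**Figure D3:**
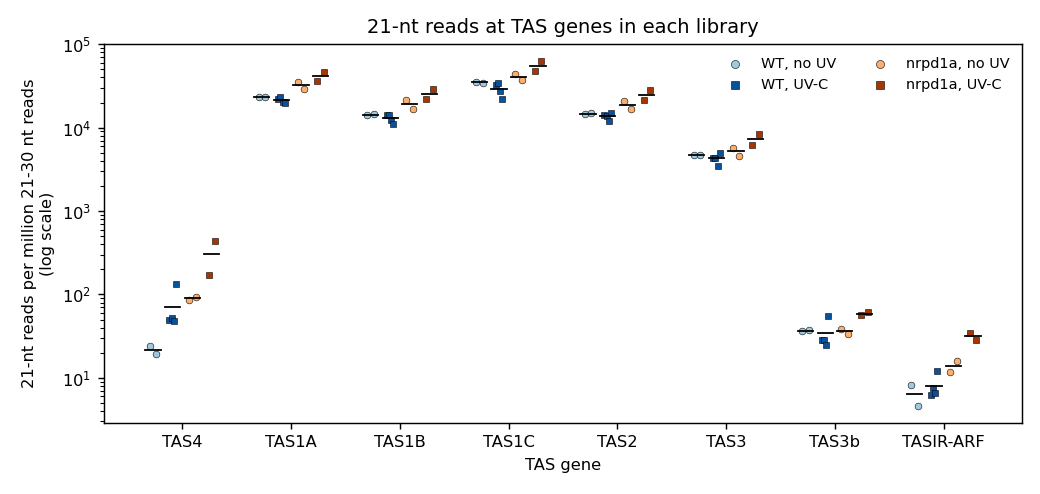
Reads of 21 nt at the TAS genes (x axis) in rpm (y axis, log scale), with points for the 10 libraries and lines for group means. TAS4 had 82 and 124 reads in WT without UV and 243 to 583 after UV.

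In nrpd1a, the same question gave 308 higher and 312 lower windows of 3771 tested at 21 nt, and 361 higher and 254 lower genes of 2241 tested. Without sequences that also match tRNA, rRNA or chloroplast, edgeR called 0 of 2989 windows (314 at an unadjusted p under 0.05) and 7 higher and 19 lower genes of 1389. With each sequence also counted once it called 0 windows (319 at an unadjusted p under 0.05) and 8 higher and 42 lower genes. Sequences at a single position gave 22 higher and 35 lower windows and 29 higher and 56 lower genes, and no filter gave 559 higher and 540 lower windows. Nuclear tRNA genes went both ways at 21 nt: 299 of 573 rose and 119 fell. All tRNA-Pro (65 of 65), tRNA-Gly (39 of 39) and tRNA-His (10 of 10) genes rose, and 64 of 65 tRNA-Tyr genes (median log2 -1.17) and 33 of 33 tRNA-Ala genes (median log2 -0.80) fell. AT3G18815 and AT4G14415 rose from 9.32 to 278 CPM on average (log2 4.85, SE 0.21, adjusted p = 7.39e-09, n = 2 each). AT4G16105 rose by log2 4.84, AT4G34975 by 4.75, AT1G49280 by 4.71, the tRNA-Gly gene AT5G02025 by 4.29 and the tRNA-Ile gene AT1G31110 by 3.45 (SE 0.14, adjusted p = 3.9e-09). AT4G22785 rose at least 18.4-fold, from 0 to 66 reads. TAS4 (log2 1.39, SE 0.27, adjusted p = 0.00178, 227 ± 38.9 to 594 ± 305 CPM) and TASIR-ARF (log2 0.85, SE 0.25, adjusted p = 0.0251) rose. Of the 8 TAS genes 2 were thus called (2 adjusted over the list alone, all 8 positive, camera adjusted p = 1). TAS4 was not called without library 1 before UV (adjusted p = 0.356) or library 2 after UV (0.0518), and TASIR-ARF without library 1 before UV (0.41) or either library after UV (0.339 and 0.0642). AGO1 had log2 0.36 (adjusted p = 0.0956), NRPD1A 0.23 and DCL1 0.06.

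Fragments of photosynthesis genes fell in nrpd1a after UV. Of 20 nuclear photosynthesis genes, 14 fell (15 adjusted over the list alone) and all 20 were negative, with a median log2 of -0.76 (camera adjusted p = 0.00109, adjusted p = 0.965 with an estimated correlation). The genes of the small subunit of Rubisco led: RBCS1A went from 196 ± 29.3 to 116 ± 6.62 CPM (SD, n = 2 each, log2 -0.76, SE 0.15, adjusted p = 0.00213). RBCS1B had log2 -1.04 (SE 0.18, adjusted p = 0.000718), RBCS3B -0.98 (adjusted p = 0.00199) and RBCS2B -0.92 (adjusted p = 0.00246). Of 126 chloroplast-encoded genes, 22 fell (20 adjusted over the list alone, median log2 -0.19, camera adjusted p = 0.0013, adjusted p = 0.82 with an estimated correlation). Among them was rbcL, the large subunit of Rubisco (1972 ± 283 to 1174 ± 148 CPM, log2 -0.75, SE 0.14, adjusted p = 0.00125). The count of photosynthesis genes was 2 without library 1 before UV, 8 and 1 without library 1 or 2 after UV, 2 with total reads as library size, 5 without sequences that also match tRNA, rRNA or chloroplast and 6 with sequences at a single position. Without library 1 before UV, RBCS1A (adjusted p = 0.0628), RBCS2B (0.0842) and rbcL (0.126) were not called, and without library 2 after UV neither were RBCS1A (adjusted p = 0.0692), RBCS2B (0.0586), RBCS3B (0.0996) and rbcL (0.066). With total reads, RBCS1A (adjusted p = 0.2), RBCS2B (0.0896) and rbcL (0.198) were not called either. The rRNA, tRNA, snRNA and snoRNA list had 299 higher and 121 lower of 653 (329 and 158 adjusted over the list alone, adjusted p = 5.36e-12, adjusted p = 0.406 with an estimated correlation). PPR genes (0 of 11, all positive although camera pointed down), auxin receptor genes (0 of 3), ARF and MYB genes (0 of 3) and RNA silencing genes (0 of 3) were not called, also over the list alone (camera adjusted p = 1 each, p under 0.05 for 769 genes in all, DESeq2 505 calls). Of the UV and stress-response genes 0 were tested.

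**Figure D4:**
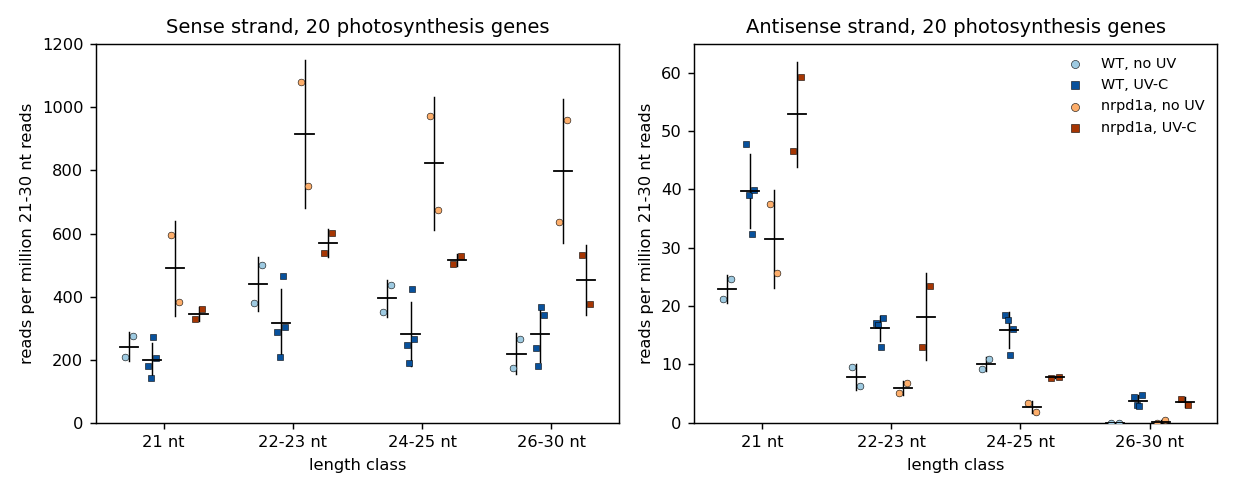
Sense and antisense reads of the 20 nuclear photosynthesis genes by length class (x axis, nt) in rpm (y axis), as group means ± SD over libraries. Over 21 to 30 nt, antisense reads had means of 40.9 and 75.6 rpm in WT without and after UV and 40.4 and 82.4 rpm in nrpd1a.

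The largest falls in nrpd1a rested on very few sequences. ACS2, MEE27, AT1G04555, AT1G11482, PGAZAT, AT3G06520, AT3G27510, AT3G43850, BGLU27 and LCR11 went from 39 to 70 listed reads to 0 (at least 28.0-fold lower for MEE27), but each held 3 to 5 reads once a sequence listed at many positions was counted once per gene. The same held for the DNA repair gene REV3 (29 reads to 1 as listed, 5 to 1 counted once), the only member of its list that was tested (1 lower, 1 over the list alone). It held too for the windows 2:11839001-11840000 (81 reads to 0), 2:9723001-9724000 (78 to 0) and 5:24741001-24742000 (78 to 0). The split of calls moved with the scale at 21 nt: total reads gave 320 higher and 153 lower windows and 427 higher and 129 lower genes, TAS reads 246 and 402 windows and 318 and 321 genes, and DESeq2 size factors 322 and 325 genes. Medians moved by 0.256 (windows) and 0.31 (genes) with total reads, and by -0.172 and -0.116 with TAS reads. At 21 nt, windows 3:6483001-6484000 (log2 5.40, SE 0.25), 4:9108001-9109000 (log2 4.91, SE 0.26) and 4:11974001-11975000 (0 to 66 reads, at least 19.1-fold) rose most. Without library 1 before UV or library 2 after UV, 355 and 388 genes were called.

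At 24-25 nt in nrpd1a, 306 windows rose and 102 fell after UV (2388 tested, 248 of the 306 with a tRNA gene). The split turned without sequences that also match tRNA, rRNA or chloroplast, with 48 higher and 117 lower, and 42 higher and 135 lower with each sequence also counted once. Sequences at a single position gave 60 higher and 32 lower. The window 2:14750001-14751000 with the tRNA-Thr gene AT2G34985 went from 3 to 104 reads. The telomere-repeat windows 2:19698001-19698289 (0 to 105 listed reads) and 3:13633001-13634000 (3 to 106) held 3 reads or fewer on either side when each sequence was counted once. The windows with the water channel gene PIP2A (3:19805001-19806000, log2 -1.73, adjusted p = 0.0373), the glycolysis and Calvin cycle gene PGK1 (3:4062001-4063000, log2 -1.66, adjusted p = 0.0214) and the small GTPase gene RABE1b (4:10991001-10992000, log2 -1.63, adjusted p = 0.0363) fell. The split was 298 and 263 with DESeq2 size factors (median moved by -0.136), 195 and 338 with TAS reads (-0.416), 279 and 39 with total reads and 241 and 341 with a filter of 30 reads. Without library 1 before UV 208 windows were called, and without library 2 after UV 258.

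The third comparison asked whether UV acted differently in the genotypes. None of 13937 windows at 21 nt and none of 4518 genes passed for the interaction (edgeR, unadjusted p under 0.05 for 1060 windows and 374 genes; DESeq2 0 and 0). These counts of 0 depended on the setting. With a filter of 30 reads 312 windows and 171 genes passed, without a filter 63 and 9, with total reads 3 windows and with TAS reads 10. Sequences at a single position gave 6 windows, each sequence counted once 8, and the latter without sequences that also match tRNA, rRNA or chloroplast 12 windows and 15 genes. At 24-25 nt, 9 of 30502 windows passed, all higher in nrpd1a (unadjusted p under 0.05 for 1744; DESeq2 43 higher and 23 lower). Total reads gave 87 windows and no filter 84. Without sequences that also match tRNA, rRNA or chloroplast 2 passed, with each sequence also counted once 0 by edgeR (1279 at an unadjusted p under 0.05), and with sequences at a single position 1 window, which was not among the 9. The window 5:11785001-11786000 with the tRNA-Asp gene AT5G32017 went from 2.42 ± 0.0608 (SD, n = 2) to 5.13 ± 0.567 CPM (n = 4) in WT. In nrpd1a it went from 9.15 ± 1.66 to 207 ± 15.1 CPM (n = 2 each; log2 of the difference 3.39, SE 0.39, adjusted p = 0.000451). The telomere-repeat windows 2:19698001-19698289 (0 reads in untreated nrpd1a) and 3:13633001-13634000 (3 reads there) passed too. Without library 4 of WT after UV the count was 291 (108 higher, 183 lower), and without library 1 of nrpd1a before UV or library 2 after UV it was 5 and 4. At 21 nt the count was 52 without library 2 of nrpd1a after UV, 17 without library 2 of untreated WT, 7 without library 1 of WT after UV and 2 without either untreated nrpd1a library, and for genes 1 without library 2 of nrpd1a after UV. Scaling moved the median interaction by 0.276 (total reads) and -0.303 (TAS reads) at 21 nt and by 0.325 (total reads) at 24-25 nt.

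As planned, no list member was called for the interaction by edgeR or by DESeq2, also over the list alone. The TAS genes were positive in 7 of 8 (median log2 0.53, camera adjusted p = 0.000666, adjusted p = 0.088 with an estimated correlation). With each sequence counted once and without sequences that also match tRNA, rRNA or chloroplast, a setting chosen after the data were seen, 5 of the 8 were called higher (median log2 0.53, camera adjusted p = 7.72e-06, adjusted p = 0.0428 with an estimated correlation). With TAS reads as library size, which hold the TAS total fixed, the median was 0.02 and 0 were called. In the planned test TAS3 was at log2 0.57, TAS1C at 0.62 and TAS4 at -0.06. The PPR genes were positive in 11 of 11 (adjusted p = 0.000156, adjusted p = 0.245 with an estimated correlation). The photosynthesis genes were negative in 19 of 20 (median log2 -0.37, adjusted p = 0.000666, adjusted p = 0.389 with an estimated correlation; RBCS2B -0.69, LHCA3 -0.84). The auxin receptor genes (adjusted p = 0.0396, adjusted p = 0.245 with an estimated correlation), the ARF and MYB genes (adjusted p = 0.0163, adjusted p = 0.163 with an estimated correlation), the RNA silencing genes (adjusted p = 0.123) and the chloroplast-encoded genes (adjusted p = 0.133) leaned upward. The rRNA, tRNA, snRNA and snoRNA genes were negative in 513 of 675 (adjusted p = 1.7e-13, adjusted p = 0.245 with an estimated correlation). REV3 and TT4 (log2 -1.64), the tested members of the DNA repair and UV lists, were not called. Calls of the separate UV tests overlapped: 256 windows at 21 nt were higher in both genotypes (325 and 307 of 3457 tested in both, 28.9 expected of independent lists). The same held for 196 at 24-25 nt (199 and 306 of 2295, 26.5 expected), and 321 genes (380 and 358 of 1972, 69.0 expected). Lower in both were 4 windows at 21 nt (0.296 expected), 0 at 24-25 nt and 1 gene (0.763 expected).

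Length-class shares did not differ after UV by the exact permutation within genotype (adjusted p = 0.967 for each of 5 classes): the mean differences were 1.499 points at 21 nt, 0.212 at 22-23 nt, -1.22 at 24-25 nt, -0.494 at 26-30 nt and -0.285 at 31-40 nt. In WT alone the 26-30-nt share was 7.78% ± 0.470 (SD, n = 2) without UV and 11.9% ± 1.83 (n = 4) after (exact permutation, 15 arrangements, p = 0.133), while in nrpd1a it was 25.9% ± 9.58 and 20.8% ± 4.26 (n = 2 each). The 21-nt share in WT alone was 17.2% ± 0.274 (n = 2) without UV and 16.2% ± 0.246 (n = 4) after, lower in every treated library (-0.948 points, exact permutation p = 0.0667, the smallest that 15 arrangements can give), against the sign of the mean over both genotypes. Among 21-nt reads, no annotation category passed for UV: the tRNA share was higher by 0.819 points (exact permutation, p = 0.0111, adjusted p = 0.111), and 4 categories passed without library 3 of WT after UV. Between genotypes the unannotated nuclear share of 21-nt reads fell by 6.65 points and the pseudogene share by 1.48 points, and the lncRNA share rose by 0.295 points (exact permutation, adjusted p = 0.037 each over 10 categories). In percent of TAS reads, a scale added after the data were seen, the first fell by 15.2, the next fell by 3.38 and the last rose by 0.650 (exact permutation, adjusted p = 0.0333 each). Of 24-25-nt reads in nrpd1a, the share of unannotated nuclear sequence fell by 53.7 points and that of pseudogenes by 7.40 points (exact permutation, adjusted p = 0.0124 each). The shares of chloroplast (by 29.8 points) and nuclear rRNA (by 28.5 points, adjusted p = 0.0124 each) rose within a total from which siRNA reads were lost. In percent of TAS reads the unannotated reads fell by 371 and the pseudogene reads fell by 52.3 (exact permutation, adjusted p = 0.0185 each), but chloroplast reads differed by 15.3 (adjusted p = 0.167) and nuclear rRNA reads by 21.7 (adjusted p = 0.21), so neither of these rises passed.

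A comparison with the DNA sequence asked whether windows that rose after UV held more of the dipyrimidines at which UV lesions form. The 327 windows had 54.9% dipyrimidines against 54.5% in matched random lists (permutation p = 0.0548 of 10000 lists). The difference passed without library 1 or 3 of WT after UV (differences 0.406 and 0.458 points), with TAS scaling (0.464), with a filter of 30 reads (0.577) and with each sequence counted once (0.507). It was smaller in 500 bp windows (0.0555, permutation p = 0.811), without library 1 or 2 of untreated WT (0.125 and 0.145, permutation p = 0.543 and 0.482) and with DESeq2 (0.246, permutation p = 0.208), and had the other sign with sequences at a single position (-0.0749, permutation p = 0.918). Windows that hold copies of one sequence entered these lists as if they were independent, so the p-values of this comparison are too small. Their GC content was 36.3% against 33.7%, 8.26% lay near centromeres against 52.0%, 75.5% overlapped protein-coding genes against 24.2% and 5.20% overlapped pseudogenes against 14.8% (each permutation p = 0.0001, the smallest that 10000 lists can give). The 30 windows without a tRNA gene, singled out after the values were seen, overlapped pseudogenes in 40.0% against 20.2% (permutation p = 0.0105) and had 37.3% GC against 33.3% (permutation p = 0.0016). Their dipyrimidines (permutation p = 0.283) and their share near centromeres (56.7% against 49.5%, permutation p = 0.464) did not differ detectably. Without sequences that also match tRNA, rRNA or chloroplast, 5 windows were left. They lay at 1:13180001-13181000, 1:13186001-13188000, 4:3733001-3734000 and 4:3753001-3754000 and held nearly the same numbers of reads in each library (101 to 118 in library 1 of WT after UV with each sequence counted once). They are not independent, so no test is given. Their differences from random lists were -5.30 points for dipyrimidines, and 48.1 points near centromeres, 66.7 for pseudogenes and -18.8 for protein-coding genes, all of the other sign than in the 327 windows. With each sequence also counted once, 17 windows with these among them differed by -2.39 points for dipyrimidines.

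The immunoprecipitation libraries asked which 21-nt positions were found with AGO1 and with DDB2. The input held 129138 positions before and 158598 after UV, the AGO1 precipitate 96574 and 121237, and the DDB2 precipitate 43908 and 50305. Per the file headers these are intergenic matches, so their shares cannot be read against the whole genome. In all 6 libraries 69.2% to 72.1% of nuclear positions lay near centromeres, against 20.98% of the nuclear genome, and unannotated nuclear sequence took 77.3%, 79.4% and 71.2% of the positions of input, AGO1 and DDB2 before UV and 77.8%, 80.0% and 72.5% after. AGO1 lay above its input there by 2.17 points before and 2.22 after UV. Without chloroplast, mitochondrial, rRNA and tRNA positions the differences were -0.26 and 0.03, within the summed half-widths of the intervals (0.39 and 0.345), so none was detectable. DDB2 positions were richer in nuclear rRNA: 14.3% (exact 95% interval 14 to 14.7) before and 13.2% (12.9 to 13.5) after UV, against 7.82% (7.68 to 7.97) and 6.82% (6.69 to 6.94) of the input and 7.04% and 6.19% of AGO1. DDB2 positions also held more snRNA or snoRNA sequence (1.33% and 1.5% against 0.756% and 0.780% of input), and both precipitates less chloroplast sequence (AGO1 0.446% and 0.472%, DDB2 0.722% and 0.626%, input 2.26% and 2.20%). Since strands are not given, the base at either end of a match was read on the plus strand. T at the leftmost base made up 42.2% of AGO1 positions before and 40.4% after UV, against 25.6% and 25.5% of input, and 33.1% and 32.5% of DDB2. A at the rightmost base made up 43.4% and 40.8% in AGO1, 25.3% and 26.2% in input, and 34.3% and 33.4% in DDB2.

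**Figure D5:**
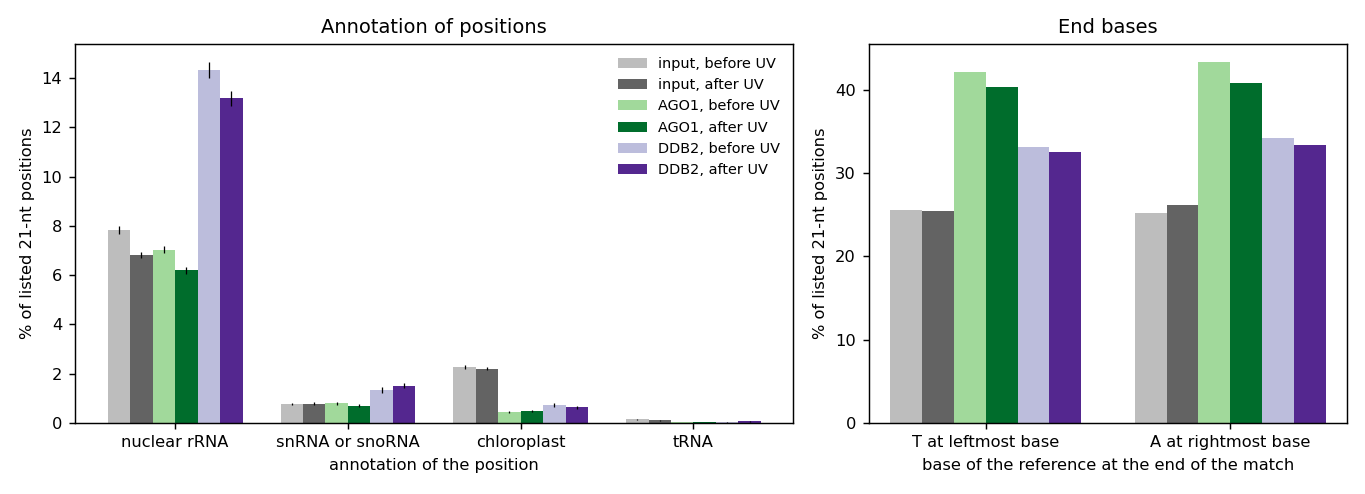
Share of listed 21-nt positions (y axis, percent) by annotation category (left) and with T at the leftmost or A at the rightmost base (right) in the 6 immunoprecipitation libraries, 1 library per bar, with exact 95% binomial intervals on the left. DDB2 bars stand at 14.3% and 13.2% in nuclear rRNA against 7.82% and 6.82% in input, and AGO1 bars at 42.2% and 40.4% for T.

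Between time points, with 1 library each and no replicate check, only 14, 12 and 7 of the 327 windows that rose after UV in WT held enough positions in the input, AGO1 and DDB2. In the input their median log2 ratio after to before UV was 0.382, at the upper 95% bound of matched random lists. The percentile was 97.7, but 91.75 with a pseudocount of 5, and 8.03 in AGO1 and 45.2 in DDB2. With no minimum, list and bounds coincided, which tests nothing. tRNA took 0.0182% of DDB2 positions before UV (8 positions) and 0.0656% after (33 positions), against 0.150% and 0.108% of input positions. Of the DDB2 positions before UV, 57.8% were also listed for AGO1 and 58.4% for input. No TAS or miRNA gene of 334 held a listed position in any of the 6 libraries. Lists of intergenic matches may leave out such genes, so this does not show their absence from the precipitates.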

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

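The weighing of explanations in this part used tests chosen only after the results were seen, whereas the interaction test was planned. TAS4 (AT3G25795), whose siRNAs target MYB genes, had 808 reads per 1000000 reads of 21 nt in library 4 of WT after UV and 297 to 330 in the other libraries of that group. TAS3b had 337 in the same library and 153 to 180 in the others. In both, the gap to the nearest library was 0.936 and 0.852 of the whole range, above Dixon's critical value for 4 samples. Of 31 groups tested these 2 stood out, and chance gives about 1 in 20. The same library differed from the rest of its group over 21-nt windows, and the rise of TAS4 in WT had its largest value there.

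At 24-25 nt the UV effects of the genotypes differed in 9 windows by the edgeR interaction test, all higher in nrpd1a. The clearest was the tRNA-Asp window 5:11785001-11786000 (interaction log2 3.39). The telomere-repeat windows among the 9 rested on 3 reads or fewer per treatment in nrpd1a with each sequence counted once. Simulated data gave 25.0% false calls for this test (4 of 16 calls), and leaving out library 4 of WT after UV gave 291 windows. Only 2 windows passed without sequences that also match tRNA, rRNA or chloroplast, and 0 with each sequence also counted once (edgeR, 1279 at an unadjusted p under 0.05).

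Nuclear tRNA-derived reads were higher after UV in every library of both genotypes (exact permutation p = 0.0111, the smallest possible, mean log2 1.39). A difference in library size or composition would move chloroplast tRNA reads too, and these differed by a mean log2 of -0.0015. General breakdown of structural RNA would raise nuclear rRNA reads, which differed by -0.183 with a wide spread (169404 ± 49660 rpm in WT after UV), whereas snRNA or snoRNA reads were higher (mean log2 0.359, exact permutation p = 0.0111, adjusted p = 0.0556). The tRNA reads rose by a log2 of 1.57 more than rRNA and 1.03 more than snRNA or snoRNA reads (exact permutation p = 0.0111 each), which argues against such breakdown as the whole rise but leaves a smaller part open. The UV treatment of the plants stays open, perhaps through cleavage of tRNAs or readier sequencing of tRNAs of other abundance or modification, neither of which was tested.

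Pseudogene windows without a tRNA gene were higher after UV in WT (ratios 4.39 to 4.93 over 5 windows), but 4 of the 5, such as 4:3733001-3734000 and 1:13187001-13188000, held nearly the same numbers of reads in each library and are in effect a single observation. In nrpd1a the median log2 of these 4 was -0.15 (SE 0.912 between libraries), and that of the separate window 4:3127001-3128000 was 0.187 (SE 0.377), which does not exclude a UV effect irrespective of genotype. The untreated nrpd1a libraries differed by a median ratio of 2.70 in the 4 windows, below the rise in WT, so a difference between libraries within a group could explain part of it there, while the separate window goes against this with a ratio of 1.08 (58 and 81 reads; 1.68 after UV) but has too few reads to exclude it. The UV effect differed between the genotypes in the 4 windows when each sequence was counted once and sequences that also match tRNA, rRNA or chloroplast were left out (edgeR interaction, log2 -2.19 to -2.06, largest adjusted p = 9.66e-08), but they were singled out by their rise in WT in the same setting, and no window passed for the interaction as planned at 21 nt. A UV effect with or without a part of the genotype therefore stays open beside the difference between libraries.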

How the results depend on the processing

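Tests with TAS reads as library size in the UV effects, with each sequence counted once, without sequences that also match tRNA, rRNA or chloroplast, and of tRNA totals, strands and categories per TAS read were chosen only after the data were seen. The other alternatives were planned. For results that answer a comparison, 124 alternatives other than leaving out a library or the block kept direction and call, 54 moved a count or value, 12 changed direction, 3 passed the threshold newly and 2 no longer passed. For single genes, windows and lists the numbers were 1048 kept, 63 moved, 14 changed direction, 10 newly past and 59 no longer past. Where not said otherwise the cause was not tested. Fewer windows and genes are tested by construction with a filter of 30 reads or with sequences at a single position.

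With sequences listed at a single position, the UV effect called 19 windows at 21 nt in WT and 57 in nrpd1a, 17 and 92 at 24-25 nt, and 17 and 85 genes, the last mostly lower. The interaction called 6 windows at 21 nt and 1 at 24-25 nt, and the genotypes differed in 1654 and 17913 windows and 499 genes. RALFL4 had log2 -6.27 and AT1G31163 -2.54, and photosynthesis genes called in nrpd1a numbered 6. Without sequences that also match tRNA, rRNA or chloroplast, edgeR called 8 windows at 21 nt in WT and 0 in nrpd1a, 0 and 165 (mostly lower) at 24-25 nt, 2 for the interaction at 24-25 nt, 0 genes in WT and 26 in nrpd1a (mostly lower), and 5 photosynthesis genes. With each sequence also counted once the counts were 20 and 0 at 21 nt, 1 and 177 (mostly lower) at 24-25 nt, 2 and 50 (mostly lower) genes, 12 and 0 windows for the interaction at 21 and 24-25 nt, and 15 genes for it. Counting each sequence once alone gave 8 interaction windows at 21 nt. By construction, most UV calls in WT thus rested on sequences that match tRNA, rRNA or chloroplast.

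Without a filter, the counts were 1099 windows at 21 nt for UV in nrpd1a, 63 for the interaction, 21780 for the genotype, 764 at 24-25 nt for UV in WT, 84 for its interaction, 9 genes for the interaction and 4376 for the genotype. With 30 reads they were 312 interaction windows and 4723 genotype windows at 21 nt, 582 windows at 24-25 nt for UV in nrpd1a (mostly lower), 171 interaction genes and 1041 genotype genes. Total reads as library size gave 3 interaction windows at 21 nt, 540 windows for UV in WT and 87 for the interaction at 24-25 nt, 3654 genotype genes and 2 photosynthesis genes in nrpd1a. TAS reads gave 10 interaction windows at 21 nt and 533 windows for UV in nrpd1a at 24-25 nt (mostly lower). TMM gave 10953 genotype windows at 24-25 nt, DESeq2 gave 66 interaction windows there, and the sense strand alone 1503 genotype genes, with AT1G31163 at log2 -2.46. Of rRNA, tRNA, snRNA and snoRNA genes between genotypes, 8 were called, against 473 with TMM, 597 with total reads and 5 without a filter, mostly higher.

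Per TAS read, the genotype difference was -0.394 at 21 nt and -96.9 at 22-23 nt, both in the other direction, 85.3 at 26-30 nt and 15.2 at 31-40 nt, in percent of TAS reads. Without chloroplast, rRNA and tRNA reads the 22-23-nt difference was -2.09 points. Dipyrimidines in windows higher after UV differed from random lists by 0.464 points with TAS scaling, 0.577 with 30 reads, 0.507 with each sequence once, -5.30 without tRNA, rRNA or chloroplast sequences and -2.39 with both. The last 2 settings gave 48.1 and 29.9 points near centromeres, -18.8 and -9.20 for protein-coding genes and 66.7 and 28.5 for pseudogenes, and a single position gave -2.43 for protein-coding genes. AGO1 minus input in unannotated nuclear positions was -0.26 without chloroplast, mitochondrial, rRNA and tRNA positions. Sense-strand genes numbered 14 with 10 reads, 19 with total reads, 17 with TAS reads and 0 with DESeq2, and antisense genes 5, 7, 4 and 0, and 0 with DESeq2 size factors.

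Leaving out 1 library gave the following ranges, in which a lone library of a group is assumed to vary like the others. At 21 nt, windows called were 243 to 344 for UV in WT, 460 to 588 in nrpd1a, 0 to 52 for the interaction and 11069 to 11633 for the genotype. At 24-25 nt they were 136 to 363, 208 to 464, 4 to 291 (mostly lower without library 4 of WT after UV) and 29062 to 29675. Genes were 270 to 403, 355 to 548, 0 to 1 and 2331 to 2426. UV differences of shares ranged from 0.293 to 2.71 points at 21 nt, -1.03 to 1.45 at 22-23 nt, -2.16 to -0.273 at 24-25 nt, -3.88 to 2.89 at 26-30 nt and -0.522 to -0.0486 at 31-40 nt, and genotype differences from 7.48 to 9.90, 0.899 to 3.38, -25.3 to -23.4, 10.14 to 16.9 and 1.53 to 2.00. Annotation categories passing for UV at 21 nt were 0 to 4, the nuclear tRNA log2 was 1.37 to 1.41, the dipyrimidine difference 0.125 to 0.458, photosynthesis genes in nrpd1a 1 to 13, their antisense log2 0.847 to 1.05, sense-strand genes 3 to 63 and antisense genes 0 to 7. The rRNA, tRNA, snRNA and snoRNA count between genotypes was 3 to 41, mostly higher without library 2 of untreated WT (5), library 3 of WT after UV (41) or library 2 of nrpd1a after UV (7).

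Replicate numbers did not pair the libraries: deviations of same-numbered libraries had correlations between -0.00464 and 0.0627. With the replicate number as a block, the interaction called 60 windows at 21 nt and 274 at 24-25 nt (mostly lower), UV in WT 818 windows at 24-25 nt, 7 photosynthesis genes in nrpd1a, 47 of the rRNA, tRNA, snRNA and snoRNA genes between genotypes (mostly higher), 67 sense-strand and 0 antisense genes, and the dipyrimidine difference was 0.403. The block kept genotype differences of 8.72 points at 21 nt, -25.3 at 24-25 nt, 14.3 at 26-30 nt and 1.82 at 31-40 nt, the tRNA log2 at 1.41 and the antisense log2 at 1.01, but its 36 arrangements cannot give an adjusted p that passes.

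Not run as planned were scaling to miRNA reads, for which TAS reads were used, shares of the total over 5 length classes, and shares with mitochondrial genes separated. Depth limits the lists of DNA repair and UV genes, of which 0 of 28 and 1 of 18 members held enough 21-nt reads for the UV test in WT. For the interaction, a simulated 4-fold change at a mean count of at least 20 was recovered in 62% of windows at 21 nt and 11% at 24-25 nt. Whether depth or the number of libraries sets this was not tested.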

Other observations

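Apart from the genotype tests, the tests in this part were chosen only after the data were seen. Genes named here were picked from the calls over both genotypes together, no test of stress genes as a group passed, and DESeq2 called none of them. Sense reads of 21 nt were found at the lipoxygenase gene LOX3 (1:5977323-5981521) 0 and 0 times in WT without UV and 6, 2, 7 and 7 times after, and 1 and 1 against 5 and 4 times in nrpd1a (adjusted p = 0.0184). LOX4 (1:27308513-27312756) had 0 and 0 against 7, 4, 6 and 1 reads in WT, and 1 and 0 against 3 and 8 in nrpd1a (adjusted p = 0.0108). OPR3 (adjusted p = 0.0474) and OPCL1 (0 and 1 against 9, 2, 8 and 3 reads in WT, 0 and 0 against 4 and 9 in nrpd1a, adjusted p = 0.00343) were called higher too. The touch-induced calmodulin-like gene TCH3 (log2 1.804, adjusted p = 0.0205) and the xyloglucan gene TCH4 (log2 1.8, SE 0.47, adjusted p = 0.0166) rose. So did the zinc finger gene STZ (adjusted p = 0.0448), the transcription factor gene WRKY40 (adjusted p = 0.0494) and the dehydration gene ERD15 (log2 0.90, adjusted p = 0.0408). Sense fragments of SBPASE (log2 -1.42, SE 0.30, adjusted p = 0.00343), SCO1 (log2 -1.22, SE 0.29), the catalase gene CAT2 (log2 -0.96, adjusted p = 0.0089), the aldolase gene FBA1 (log2 -0.95), the chlorophyll gene GUN5 (log2 -0.77) and RBCS1B (log2 -0.68) fell. In all, 17 genes rose and 20 fell of 2212 tested over both genotypes with edgeR at a minimum of 5 reads.

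These counts were small and the calls fragile. A minimum of 10 reads gave 14 of 966 genes (1 higher), and DESeq2 gave 0 (135 genes at an unadjusted p under 0.05, 257 with edgeR). The interaction gave 0 genes with edgeR (99 at an unadjusted p under 0.05), WT alone 0 (101), and nrpd1a alone 7 higher and 36 lower of 1255. Without library 2 of nrpd1a after UV 3 genes were called, and without library 3 of WT after UV 63. Among 90 arrangements of labels within genotype, 4 gave as many genes, the real one with 37 included, and the highest other gave 48, a share under the threshold of 0.05. With the minimum of 10 reads 6 arrangements gave as many as the real 14, and the highest other gave 79. The cause of that higher count was not tested. Chance is therefore not excluded for the sense-strand calls. Simulated 2-fold and 4-fold changes were recovered for 77% and 99% of sense-strand genes.

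Antisense reads of the 20 nuclear photosynthesis genes, which encode the light-harvesting and carbon-fixing proteins, were higher in every treated library than in the untreated ones of its genotype, without passing the adjusted test. Antisense reads of 21 to 30 nt went from 40.9 ± 1.23 (SD, n = 2) to 75.6 ± 11.69 rpm (n = 4) in WT and from 40.4 ± 7.88 to 82.4 ± 15.8 rpm (n = 2 each) in nrpd1a. The exact permutation gave p = 0.0111, the smallest possible, but adjusted p = 0.0617 over 50 tests, so the rise did not pass. Sense reads of the same genes differed by a mean log2 of -0.49 (exact permutation p = 0.0889, adjusted p = 0.234), and at 26-30 nt they were higher in WT (log2 0.33) and lower in nrpd1a (log2 -0.81). By edgeR at 21 nt, 1 of 18 genes was called on the antisense strand (8 adjusted over the list alone), RBCS2B (log2 0.86, adjusted p = 0.029), all 18 were positive, and the list stood apart also with an estimated correlation (camera p = 0.00376 without adjustment for other tests). On the sense strand 4 of 20 were lower (12 over the list alone) and all 20 negative (camera p = 1.35e-13, and p = 0.0763 with an estimated correlation, both without adjustment).

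Errors of strand made from sense reads would follow the sense reads, which differed by a mean log2 of -0.491. A shift of scale or a general rise of antisense reads would move other genes alike, and the antisense reads of 100 other genes moved less, by a mean log2 of 0.712 (exact permutation over both genotypes, p = 0.0111). The few antisense reads of the UV and stress-response genes were higher by as much (mean log2 1.053, exact permutation p = 0.0111), so the rise is not shown to be particular to photosynthesis genes. The difference to the 100 genes was 0.946 in WT, which argues there against a proportional rise of all antisense reads as the whole cause. It was 0.478 in nrpd1a, below the bound of 0.5 set for the test, so a general rise of antisense reads stays open in nrpd1a. The 100 genes held 493096 antisense reads in all libraries against 2814 of the photosynthesis genes. A rise of a few reads per gene would therefore not show in them. At 26-30 nt, antisense reads of all other nuclear protein-coding genes were higher by log2 0.711 in WT and 0.621 in nrpd1a. The exact permutation gave p = 0.0222 there (adjusted p = 0.101), so a general rise at that length stays open. The UV treatment of the plants (exact permutation p = 0.0111) stays open, and transcription or copying of photosynthesis transcripts from the opposite strand after UV may be involved, which was not tested. Over all genes, 1 antisense call (RBCS2B) was matched by 30 of 90 arrangements (highest other 4), so chance cannot be excluded for that count. With a minimum of 10 reads 2 of 90 reached the real count of 5 (highest other 6), so this depended on the minimum. DESeq2 called 0 (21 at an unadjusted p under 0.05, 85 with edgeR).

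The 18 UV and stress-response genes had sense reads of 16.4 ± 2.11 (SD, n = 2) and 33.5 ± 5.48 rpm (n = 4) in WT without and after UV and 31.8 ± 4.22 and 44.1 ± 4.38 rpm (n = 2 each) in nrpd1a (exact permutation p = 0.0111, adjusted p = 0.0617). Their antisense reads, 144 in all libraries, were 2.26 ± 0.739 (n = 2) and 4.32 ± 0.941 rpm (n = 4) in WT and 1.38 ± 0.439 and 3.69 ± 1.72 rpm (n = 2 each) in nrpd1a (log2 0.877 and 1.229, exact permutation p = 0.0111, adjusted p = 0.0617). Mitochondrial reads, counted at each match, were 10172 ± 340 rpm (SD, n = 2) in WT and 18803 ± 1133 (n = 2) in nrpd1a without UV, in a total that lost siRNAs. Exact permutation gave mean log2 0.75 for genotype (p = 0.0111) and -0.10 for UV (p = 0.511).

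Of 210 possible assignments of the 10 libraries to genotypes, 100 were drawn for each planned genotype test, the real one included. The assignment equal to the UV treatment was left out before the draw. Of these 100, 1, the real one, reached its count: 11627 windows at 21 nt (highest other 8137), 29528 windows at 24-25 nt (highest other 27371) and 2434 genes (highest other 0). Chance can therefore be excluded for these counts.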
